A study of Homo sapiens with 9 samples.

How the data were processed

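White blood cells of 2 subjects with food protein-induced enterocolitis syndrome, a food allergy not driven by IgE antibodies, were profiled by single-cell RNA sequencing with 10x Genomics 3′ chemistry. Per the labels, white cells from 6 ml of blood were freed of red cells by lysis, spread over 23 wells of 12-well plates in medium with 10% serum, and given 1 homogenized food each at 1 mg per ml, lipopolysaccharide (LPS) or nothing. The 9 libraries analysed were untreated, LPS and rice wells of both subjects, cow milk and almond butter wells of subject A, and a scrambled eggs well of subject B. Each well was sequenced as 1 library, and the labels give neither the LPS dose, nor the length of treatment, nor which foods the subjects react to.

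The deposited matrices hold whole-number UMI counts per gene and cell barcode, per the file headers, for 36601 genes. The headers name Cell Ranger 4.0.0 for the 5 libraries of subject A and 6.1.2 for the 4 of subject B, while the submitters' notes name Cell Ranger 2.1.1 and hg38 for all 9. The gene annotation is not stated, and the software version cannot be told apart from the subject, so contrasts were taken within subjects. Genes carry the symbols and Ensembl IDs that the files pair, without positions. Libraries hold 31505000 to 68418622 UMIs in 4234 to 7978 barcodes of at least 500 UMIs each. Left out throughout, by a rule, were 766 genes (0.229% of UMIs): X-inactivation and Y-linked genes, T cell receptor and immunoglobulin segments, and genes whose level follows a person's genotype (HLA-DRB, HLA-DQ, KIR and some glutathione transferase genes among them).

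Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold called 0 to 8 cells in 7 of the 9 libraries, so the cells with the highest scores were removed instead, up to an expected share of 0.8% per 1000 cells. That left 3857 to 7237 cells per library. Counts were scaled per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, scikit-learn 1.9.0) gave 32 clusters over the 9 libraries together, with no batch correction. Among the marker lists with at least 3 markers detected in 10% of a cluster's cells, the one with the highest score gave the name if its margin to the next of them was at least 0.2. Cluster 14, at 0.172 of its libraries' median UMIs and with none of its markers among its top genes against all other cells, stayed unnamed by a rule on depth. The marker lists covered T-like, NK-like, B-like, plasma-cell-like, monocyte-like, neutrophil-like, conventional-dendritic-like, plasmacytoid-dendritic-like, basophil-or-mast-like, eosinophil-like, platelet-like, erythroid-like and progenitor-like cells. No cluster took the basophil-or-mast-like, eosinophil-like, erythroid-like or progenitor-like name. Class shares are given per library with exact Clopper-Pearson 95% intervals. They were not tested: with 2 subjects an exact rank test allows no two-sided p below 0.333 unpaired or 0.5 paired, and no model of the shares was fitted.

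UMI counts were summed per library and class, and classes with at least 50 cells in each of the 6 untreated, LPS and rice libraries were tested. These were monocyte-like (74 cells in the smallest library), T-like (3516), NK-like (159) and B-like cells (753). LPS and rice were compared with untreated, and rice with LPS, in edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with subject as a block and 2 residual degrees of freedom. Adjusted p values are Benjamini-Hochberg values within class and contrast, called under 0.05. Errors are standard errors (SE) for log2 fold changes and standard deviations (SD) over 2 libraries for mean CPM, with CPM scaled by TMM. To check the block, residuals were correlated within subjects (0.288 to 0.801 across classes and contrasts). Replicate libraries of 1 treatment differed by far more than counting error over all classes summed (chi-square per gene 59.4 to 97.8), so counting intervals alone understate the error. Tested on simulated data with 200 changed genes, the fit recovered 55% of changes of 1 log2 unit and 97% of changes of 2 in monocyte-like cells, with 8 false calls. In T-like cells it recovered 100% of both, in NK-like cells 74% and 100%, and in B-like cells 97% and 100%.

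Fixed gene lists, 19 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. They covered inflammatory cytokines and chemokines, NF-kB feedback and survival, interferon-stimulated genes, MHC class II presentation, monocyte alarmins and resting genes, inflammasome and pyroptosis, fatty acid response, cholesterol synthesis, heat shock proteins, metallothioneins and metal transport, glycolysis and hypoxia, oxidative stress response, unfolded protein and amino acid stress, immediate early genes, T cell activation, T helper cytokines, cytotoxic effectors, B cell activation and proliferation. Member counts are over all genes tested, and separately adjusted over the list alone. Of the camera calls, only those of the T helper cytokines in T-like cells with LPS, of T cell activation and T helper cytokines in NK-like cells with LPS, and of heat shock proteins in NK-like cells with rice held with a correlation estimated from the libraries. The overlap of LPS and rice calls was set beside the number that independence gives and beside 100 simulations of unchanged groups sharing the untreated libraries.

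Genes were named by rules fixed with the lists, tests, markers and contrasts before the data were examined. For the tested contrasts these were the 10 genes highest and the 10 lowest in log2 fold change in monocyte-like cells, and 4 per side in the other classes. They were taken among called genes with at least 50 CPM in the higher group and the same sign in both subjects. For foods with 1 library they were the 8 highest and 8 lowest log2 ratios in monocyte-like cells and 4 per side in T-like cells, among genes with at least 100 CPM and 50 UMIs in the higher library. Members of the lists could be named as examples. Ribosomal, mitochondrial and clone-named genes were passed over. Cow milk, almond butter and scrambled eggs have no replicate, so they have no test, SE or count of changed genes. Their CPM, not scaled by TMM, were set beside those of the same subject's untreated and LPS libraries with exact Poisson 95% intervals, which cover counting error only. List medians are of log2 ratios with 10 CPM added, over members with at least 10 CPM, beside the percentile among 10000 random lists matched on expression. A fold against a group without a UMI is a lower bound from 3 counts over the group, and genes with 1 to 3 UMIs in the reference have a pooled ratio with its counting interval.

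The alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, no subject block, only the 4 libraries of a contrast, leaving out each library in turn, doublets kept, a stricter cell filter (500 genes, 10% mitochondrial UMIs), Leiden resolution 0.5 (22 clusters), an estimated correlation for camera, and 1 or 50 CPM added for the single foods. Doublets by the automatic threshold were added as an alternative after the data were seen, as were the interferon, heat shock, metallothionein and immediate early lists in classes they had not been fixed for. Where a left-out library leaves its group with 1 library, that library was assumed to vary like the other groups. Differences between the subjects were not tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.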

Results

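Gene expression was measured in single white blood cells from 9 wells of 2 subjects. Untreated, LPS and rice had 2 libraries each, and cow milk, almond butter and scrambled eggs had 1 each. LPS, the cell wall lipid of Gram-negative bacteria that monocytes sense through TLR4, was the positive control. In subject A the total was 68418622 UMIs untreated, 43131172 with LPS, 48863973 with milk, 40063415 with rice and 31505000 with almond butter. In subject B it was 49451504 UMIs untreated, 46202103 with LPS, 38079036 with eggs and 42948859 with rice. Cells analysed per library, in the same order, numbered 7237, 4739, 6609, 4964 and 3857 in subject A and 6062, 5796, 4871 and 5515 in subject B. Median depth was 6309 to 8041 UMIs per cell.

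Monocyte-like cells were a smaller share of the LPS and rice libraries than of the untreated ones in both subjects. They made up 4.08% (3.63% to 4.56%) of cells untreated, 2.22% (1.82% to 2.68%) with LPS and 1.49% (1.17% to 1.87%) with rice in subject A, where the brackets hold 95% intervals. In subject B these shares were 3.98% (3.5% to 4.5%), 1.83% (1.5% to 2.21%) and 2.21% (1.84% to 2.64%). Milk, almond butter and eggs left them at 3.89%, 4.07% and 4.7%. T-like cells held 68.7% to 74.2% of each library and B-like cells 12.5% to 16.0%. NK-like cells held 3.36% to 3.79% in subject A and 6.16% to 7.65% in subject B. The intervals count cells only, and no share was tested.

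**Figure D1:**
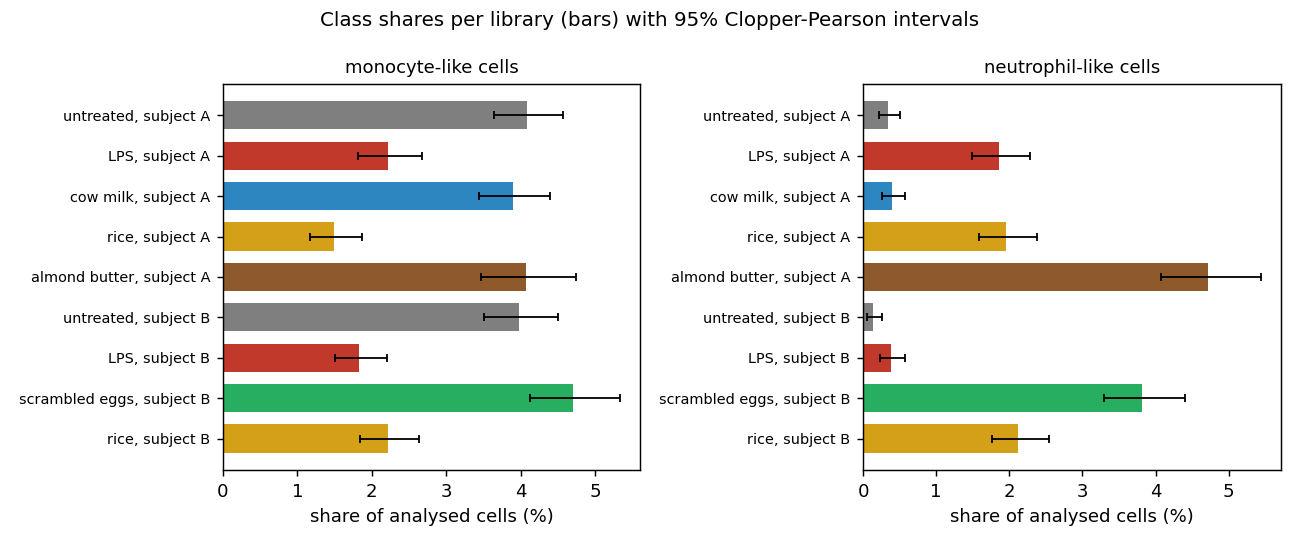
Share of analysed cells (percent) per library for monocyte-like and neutrophil-like cells, with bars for the 9 libraries and exact Clopper-Pearson 95% intervals as error bars. Monocyte-like cells stand at 4.08% and 3.98% untreated and at 2.22% and 1.83% with LPS.

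LPS against untreated asked what a bacterial stimulus did to the same blood. In monocyte-like cells LPS raised inflammatory cytokines and chemokines, the signals that recruit and activate other white cells, by large factors. CCL3 and CCL4, chemokines that attract monocytes and T cells, rose by 9.51 ± 0.61 and 7.88 ± 0.14 log2 units (± SE, n = 2), from 48.6 ± 19.2 to 11426 ± 4129 CPM (± SD) for CCL4. IL1B (ENSG00000125538), the pyrogenic interleukin, rose by 7.55 ± 0.22, to 28975 ± 2989 CPM from 156 ± 14.7. IL6 (ENSG00000136244), the acute-phase cytokine, reached 1400.2 ± 615 CPM from 1 UMI over both untreated libraries together, a pooled ratio of 9484 (counting interval 1701 to 374695). IL12B, a subunit of interleukins 12 and 23, had no UMI untreated and was at least 119-fold higher with LPS, at 55.2 CPM, though DESeq2 did not call it (adjusted p = 0.117). Of 24 cytokine genes tested, 23 rose and none fell (24 rose adjusted over the list alone), with a median of 5.99 that stayed the same with IL12B at its bound. The list test gave an adjusted p = 2.6e-55, and adjusted p = 0.301 with an estimated correlation. OSM was not called (0.59 ± 0.25).

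The other genes highest with LPS in monocyte-like cells were INHBA, which encodes an activin subunit (9.12 ± 0.32), IL36G, an interleukin of the IL-1 family (8.73 ± 0.43), DNAAF1 (8.22 ± 0.47), MIR155HG, the host gene of microRNA-155 (8.08 ± 0.39), and CCL4L2 (7.95 ± 0.20). CSF3, a granulocyte growth factor, had 1 UMI untreated and 111 ± 61.6 CPM with LPS, a ratio of 726 (129 to 28768). CCL4L2 is a near-identical copy of CCL4, as CCL3L1 is of CCL3, so the split of UMIs within each pair is uncertain. Lowest were SDS, a serine-degrading enzyme, which fell by 6.59 ± 0.52 from 186 ± 52.5 to 1.89 ± 0.421 CPM, and FUCA1, a lysosomal fucosidase, which fell by 5.17 ± 0.55. LYL1 (-4.75 ± 0.47), AVPI1 (-3.84 ± 0.41), PHF23 (-3.66 ± 0.34), RGS19 (-3.52 ± 0.39), INAFM2 (-3.51 ± 0.44), SCIN (-3.45 ± 0.36), SLC16A10 (-3.44 ± 0.30) and OTOA (-3.44 ± 0.53) fell too. In all, 2755 of 8397 genes tested were called by edgeR, 1562 up and 1193 down. All LPS monocyte-like cells of both subjects lay in cluster 22, while cluster 13 held 99% and 98.8% of the untreated ones. Leaving out the untreated library of subject A lowered the count to 1743, and no named gene lost its call in any left-out fit.

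NF-kB targets, which feed back on the signal and keep monocytes alive, rose in 18 of 21 (20 adjusted over the list alone), with a median of 2.26 (adjusted p = 9.35e-24, and adjusted p = 0.371 with an estimated correlation). TNIP3 rose by 7.44 ± 0.29, TRAF1 by 5.37 ± 0.29 and the costimulatory receptor CD40 by 5.37 ± 0.36, while BCL3, NFKBIE and RELB were not called. Interferon-stimulated genes, the antiviral program, rose in 30 of 32 (30 adjusted over the list alone), with a median of 3.64 (adjusted p = 5.68e-28, and adjusted p = 0.371 with an estimated correlation). OASL rose by 6.06 ± 0.45, IFIT3 by 5.89 ± 0.22 and IFIT2 by 5.73 ± 0.35, while IFITM3 and LY6E were not called. Among inflammasome genes, NLRP3, the sensor, rose by 4.56 ± 0.26 and CASP1, the protease that matures IL-1β, by 2.14 ± 0.21, while NAIP fell by 2.05 ± 0.26. There 5 of 10 rose and 2 fell, the same adjusted over the list alone, with a median of 0.77 (adjusted p = 0.0177, and adjusted p = 0.371 with an estimated correlation). Heat shock proteins, the chaperones of misfolded protein, rose in 6 of 14 (8 adjusted over the list alone), DNAJB4 by 2.05 ± 0.35, with a median of 0.64 (adjusted p = 0.0386, and adjusted p = 0.741 with an estimated correlation).

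The remaining lists were not called as a whole in monocyte-like cells with LPS, though members moved. Of MHC class II genes, which present antigen, 5 rose and 1 fell of 11 (6 and 1 adjusted over the list alone), with a median of 0.93 (adjusted p = 0.103). HLA-DRA rose by 1.32 ± 0.11 and HLA-DPB1 by 1.40 ± 0.15, while the lysosomal reductase IFI30 fell by 1.56 ± 0.18. Of monocyte alarmins and resting genes, 6 rose and 2 fell of 18 (7 and 4 adjusted over the list alone, median -0.06, adjusted p = 0.731), with MNDA at 3.06 ± 0.37, the alarmin S100A8 at 1.70 ± 0.18 and the LPS co-receptor CD14 at -1.34 ± 0.34. Of fatty acid genes, 3 rose and 3 fell of 11 (3 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.464), with G0S2 at 3.35 ± 0.18 and the lipid droplet coat PLIN2 at -2.16 ± 0.25. Of cholesterol synthesis genes, 5 rose and 1 fell of 14 (5 and 2 adjusted over the list alone, median 0.58, adjusted p = 0.0584), and the list was called without the subject block (adjusted p = 0.0358). Of metallothioneins and metal transporters, 1 rose and 1 fell of 9 (1 and 1 adjusted over the list alone, median -0.38, adjusted p = 0.731), the zinc importer SLC39A8 rising by 3.16 ± 0.22. Of glycolysis genes, 3 rose and 4 fell of 20 (3 and 4 adjusted over the list alone, median 0.15, adjusted p = 0.915), with PFKFB3 at 1.84 ± 0.19 and the lactate exporter SLC16A3 at -1.36 ± 0.21. Of oxidative stress genes, 5 rose and 1 fell of 14 (8 and 2 adjusted over the list alone, median 0.76, adjusted p = 0.167), with thioredoxin TXN at 2.24 ± 0.17 and the heme-degrading HMOX1 at -1.98 ± 0.56. Of unfolded protein genes, 6 rose and 2 fell of 14 (7 and 2 adjusted over the list alone, median 0.53, adjusted p = 0.0683), with PPP1R15A at 2.44 ± 0.18 and ATF3 at -1.34 ± 0.30. Of immediate early genes, 8 rose and 2 fell of 19 (8 and 2 adjusted over the list alone, median 0.56, adjusted p = 0.127), with DUSP2 at 2.81 ± 0.24 and FOS at -1.12 ± 0.26. The median and the camera direction differed in sign for the metallothionein, fatty acid and alarmin lists, where the test pointed up, and for glycolysis, where it pointed down.

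T-like cells, the largest class, answered LPS with the interferon program. IFIT3, an antiviral RNA-binding protein, rose by 6.77 ± 0.45 log2 units, from 2.17 ± 1.12 to 299 ± 346 CPM, IFIT1 by 6.76 ± 0.60, OAS1 by 6.34 ± 0.40 and IFI44L by 6.06 ± 0.40. Of 32 interferon-stimulated genes, 23 rose and none fell (32 rose adjusted over the list alone, median 3.41, adjusted p = 1.79e-102, and adjusted p = 0.0694 with an estimated correlation). Only 4 of 15 T helper cytokine genes passed the filter. All rose (4 adjusted over the list alone), among them lymphotoxins LTA by 2.69 ± 0.12 and LTB by 1.00 ± 0.05, and IFNG by 1.14 ± 0.21 (list median 1.91, adjusted p = 5.87e-29, and 0.0378 with an estimated correlation). T cell activation genes rose in 4 of 18 (9 adjusted over the list alone), BATF by 2.29 ± 0.24 and the early activation marker CD69 by 1.61 ± 0.20 (list median 0.39, adjusted p = 1.64e-10, and adjusted p = 0.0694 with an estimated correlation). No cytotoxic effector of 14 and no proliferation gene of 19 was called by edgeR, also adjusted over the list alone, with medians of -0.02 (adjusted p = 0.709) and -0.16 (adjusted p = 0.0317, and adjusted p = 0.232 with an estimated correlation). WAKMAR2 (-0.81 ± 0.12), ID3 (-0.51 ± 0.08), CTSD (-0.49 ± 0.09) and MAPRE2 (-0.37 ± 0.07) fell. In all, 395 of 14955 genes were called, 369 up and 26 down.

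The T-like count with LPS rested on single libraries and on the subject block. It was 779 without the LPS library of subject B, 223 without the rice library of subject A and 83 without the untreated library of subject A. Without the block edgeR called 0 genes (613 at an unadjusted p under 0.05) and DESeq2, with the block, called 456. The 4 genes that fell lost their calls in 2 to 6 of the 6 left-out fits: WAKMAR2 without rice A (adjusted p = 0.0591) or untreated A (adjusted p = 0.138), ID3 without untreated A, LPS A, rice A or untreated B, CTSD without untreated A, LPS A, rice A or rice B, and MAPRE2 without any 1 of the 6 (adjusted p = 0.0543 to 0.480). With only the 4 LPS and untreated libraries fitted none of these 4 was called (adjusted p = 0.0586 to 0.103). T-like cells lay in clusters 4, 17 and 20 in the LPS library of subject A (56.4%, 15.1% and 11.7%), against cluster 0 in its untreated library (55.9%). In subject B cluster 1 was the largest in both (36.6% and 38.6%).

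NK-like cells raised interferon-stimulated genes and activation receptors with LPS. RSAD2, the antiviral enzyme viperin, rose by 6.74 ± 0.27, IFI44L by 6.80 ± 0.40, OAS1 by 5.62 ± 0.34 and IFIT1 by 5.52 ± 0.34. T cell activation genes rose in 9 of 12 (9 adjusted over the list alone), TNFRSF9 by 3.01 ± 0.26 and CD69 by 1.34 ± 0.13 (list median 1.04, adjusted p = 5.93e-21, and adjusted p = 0.0293 with an estimated correlation). T helper cytokines, 4 of 15 tested, rose in 3 (3 adjusted over the list alone), IFNG by 2.28 ± 0.23, to 158 ± 83.7 CPM from 30.7 ± 5.47 (list median 1.94, adjusted p = 1.35e-10, and 0.0369 with an estimated correlation). Cytotoxic effectors rose in 3 of 14 (3 adjusted over the list alone), the granzyme GZMA by 0.85 ± 0.12 (list median 0.16, adjusted p = 0.00964, and adjusted p = 0.387 with an estimated correlation), and the list's adjusted p = 0.0515 without the subject block. TTC38 (-1.52 ± 0.19), KRT81 (-1.16 ± 0.16), RHOBTB3 (-0.98 ± 0.18) and TBC1D2B (-0.95 ± 0.22) fell. In all, 410 of 9669 genes were called, 341 up and 69 down, and 6 without the block. The count was 248 without the LPS library of subject A and 261 without the untreated library of subject A. TBC1D2B lost its call without LPS A (adjusted p = 0.235) or untreated A (adjusted p = 0.328), and DESeq2 called neither it (adjusted p = 0.247) nor RHOBTB3 (adjusted p = 0.0966).

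The genes highest in B-like cells with LPS were interferon-stimulated. IFIT1 stood at 670.2 CPM with LPS and 0.702 untreated in subject A, and at 59.7 against no UMI in subject B (fitted log2 fold change 9.94 ± 0.25). RSAD2 rose by 8.07 ± 0.24, IFI44L by 6.71 ± 0.39 and IFIT3 by 6.59 ± 0.24, and with DESeq2 IFI44L was not called (adjusted p = 0.284). B cell activation genes had no edgeR call among 12 (5 rose adjusted over the list alone, median 0.52, adjusted p = 7.35e-06, and adjusted p = 0.251 with an estimated correlation). Proliferation genes had none among 13, also adjusted over the list alone (list median -0.03, adjusted p = 0.468). In all, 109 of 11388 genes rose and none fell, and without the subject block edgeR called 0 (267 at an unadjusted p under 0.05), while DESeq2 with the block called 66. The count was 35 without the untreated library of subject A, 175 without that of subject B, 276 and 266 without the rice libraries of A and B, and 717 without the LPS library of subject B. Cluster 18 held 73.5% of B-like cells in the LPS library of subject A, where cluster 3 held 87.4% untreated. In subject B cluster 3 held 83.4% with LPS and 91.6% untreated.

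Rice, the food given to both subjects, was compared with untreated to see what a food alone did to these cells. Of the 986 genes that rose in monocyte-like cells, 865 also rose with LPS. IL1B rose by 6.33 ± 0.21, to 12731 ± 3710.5 CPM from 156 ± 14.7 untreated, CCL3 by 8.23 ± 0.58, CCL4 by 7.07 ± 0.13 and the chemokine CCL20 by 6.79 ± 0.31. IL6 reached 317 ± 192 CPM, a pooled ratio of 2059.5 (369 to 81452). Of 24 cytokine genes 19 rose and none fell (19 adjusted over the list alone, median 4.63, adjusted p = 1.17e-57, and adjusted p = 0.224 with an estimated correlation). The median was 5.05 with IL12B left out, which had no UMI with rice or untreated. CCL2 (0.31 ± 0.23), CCL7 (0.79 ± 0.44), the anti-inflammatory IL10 (0.55 ± 0.28) and OSM (0.27 ± 0.25) were not called.

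The other genes highest with rice in monocyte-like cells were INHBA (8.51 ± 0.32), DNAAF1 (7.03 ± 0.46), CCL4L2 (6.97 ± 0.19), MIR155HG (6.49 ± 0.39) and F3, the tissue factor that starts clotting (6.12 ± 0.43). Lowest were SDS, which fell by 4.09 ± 0.40, RGS19 (-2.71 ± 0.35), NLRP12 (-2.67 ± 0.39), ANKH (-2.65 ± 0.59), FUCA1 (-2.64 ± 0.42), the lysosomal nuclease DNASE2 (-2.59 ± 0.44), LYL1 (-2.44 ± 0.35), TNRC18 (-2.40 ± 0.48), TNS1 (-2.32 ± 0.29) and the chemokine receptor CXCR4 (-2.38 ± 0.33, from 610.5 ± 154 to 119 ± 73.5 CPM). In all, 1400 genes were called, 986 up and 414 down, and 697 without the subject block, where ANKH and FUCA1 were no longer called. ANKH was not called by DESeq2 (adjusted p = 0.181). The count was 668 without the rice library of subject A, 886 without that of subject B and 917 without the untreated library of subject B. Cluster 22, which held the LPS cells, held 93.2% of rice monocyte-like cells in subject A and 60.7% in subject B, the rest lying with the untreated cells in cluster 13.

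NF-kB targets rose with rice in 19 of 21 (19 adjusted over the list alone), TNIP3 by 5.80 ± 0.28, TRAF1 by 4.54 ± 0.29 and BCL2A1 by 3.55 ± 0.27 (list median 1.83, adjusted p = 9.57e-25, and adjusted p = 0.306 with an estimated correlation). Heat shock proteins rose in 13 of 14 (14 adjusted over the list alone), DNAJB4 by 2.63 ± 0.36, HSPA1B by 2.18 ± 0.36 and BAG3 by 1.89 ± 0.33 (list median 1.24, adjusted p = 4.57e-08, and adjusted p = 0.308 with an estimated correlation). HSPA1A and HSPA1B are near-identical copies whose UMIs cannot be split with certainty. Interferon-stimulated genes rose in 7 of 32 (9 adjusted over the list alone), OASL by 3.58 ± 0.46 and IFIH1 by 1.18 ± 0.21 (list median 0.59, adjusted p = 0.00152, and adjusted p = 0.554 with an estimated correlation). Immediate early genes, the first transcribed after a stimulus, rose in 9 of 19 (9 adjusted over the list alone), EGR3 by 4.90 ± 0.36 and EGR2 by 3.89 ± 0.56 (list median 0.76, adjusted p = 2.86e-05, and adjusted p = 0.28 with an estimated correlation). Oxidative stress genes rose in 8 of 14 (10 adjusted over the list alone), OSGIN1 by 2.23 ± 0.37 and TXN by 1.99 ± 0.17 (list median 1.18, adjusted p = 0.00021, and adjusted p = 0.418 with an estimated correlation).

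Inflammasome genes rose with rice in 5 of 10 and fell in 2 (6 and 2 adjusted over the list alone), with GBP2 at 3.26 ± 0.23, NLRP3 at 3.17 ± 0.26 and NAIP at -1.95 ± 0.26 (list median 0.99, adjusted p = 0.000876, and adjusted p = 0.305 with an estimated correlation). Fatty acid genes rose in 4 of 11 (4 rose and 1 fell adjusted over the list alone), G0S2 by 2.78 ± 0.17 and ACSL1 by 2.13 ± 0.21 (list median 0.55, adjusted p = 0.00754, and adjusted p = 0.306 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 14 (5 adjusted over the list alone, median 0.53, adjusted p = 0.0202, and adjusted p = 0.306 with an estimated correlation). Metallothioneins and metal transporters rose in 4 of 9 (5 adjusted over the list alone), SLC39A8 by 2.69 ± 0.22 and the zinc-binding MT2A by 1.16 ± 0.25 (list median 0.48, adjusted p = 0.0481, and adjusted p = 0.306 with an estimated correlation). The other lists were not called. Of MHC class II genes, 1 rose and 2 fell of 11 (1 and 2 adjusted over the list alone, median -0.01, adjusted p = 0.515), with HLA-DRA at 0.61 ± 0.11 and IFI30 at -0.95 ± 0.18. Of alarmins, 3 rose and 0 fell of 18 (4 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.515), with MNDA at 2.28 ± 0.37. Of glycolysis genes, 3 rose and 1 fell of 20 (3 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.664), with ADM at 1.10 ± 0.18 and HK2 at -1.06 ± 0.18. Of unfolded protein genes, 3 rose and 0 fell of 14 (3 and 0 adjusted over the list alone, median 0.38, adjusted p = 0.0659), with PPP1R15A at 1.98 ± 0.18.

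T-like cells raised NF-kB subunits and a heat shock gene with rice. RELB rose by 2.09 ± 0.12, from 21.5 ± 1.41 to 92.2 ± 16.7 CPM, NFKB2 by 1.98 ± 0.13, the chaperone HSPA1A by 1.92 ± 0.19 and BCL3 by 1.53 ± 0.22. The zinc-binding metallothioneins MT1X (-1.04 ± 0.16) and MT1E (-0.92 ± 0.10) fell, as did WAKMAR2 (-0.80 ± 0.12) and the protease CTSD (-0.71 ± 0.09). The MT1 genes are close copies, so their UMIs are assigned with uncertainty. T helper cytokines rose in 2 of 4 (4 adjusted over the list alone), LTA by 1.99 ± 0.12 and LTB by 0.82 ± 0.05 (list median 1.41, adjusted p = 2.42e-17, and adjusted p = 0.0634 with an estimated correlation). Interferon-stimulated genes rose in 2 of 32, IFIT3 and OAS3 (6 adjusted over the list alone, median 0.71, adjusted p = 1.73e-10, and adjusted p = 0.487 with an estimated correlation). T cell activation genes had no edgeR call among 18 (4 adjusted over the list alone, median 0.14, adjusted p = 0.00773, and adjusted p = 0.429 with an estimated correlation). Cytotoxic effectors and proliferation genes had no call, also adjusted over the list alone, with medians of 0.07 and -0.05 (adjusted p = 0.575 and adjusted p = 0.575).

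In all, 111 genes of T-like cells were called with rice, 102 up and 9 down, and the count moved with most libraries. It was 441 and 383 without the LPS libraries of A and B, 11 without the rice library of subject A and 3 without the untreated library of subject A. Without the subject block edgeR called 0 (438 at an unadjusted p under 0.05), and DESeq2 called 278 with it. RELB was called in every left-out fit. NFKB2 was not called without rice A (adjusted p = 0.0733) nor HSPA1A without untreated A (adjusted p = 0.204). BCL3, MT1X, MT1E, WAKMAR2 and CTSD each lost their calls without untreated A, rice A or rice B (adjusted p = 0.0594 to 0.496). WAKMAR2 was also not called with DESeq2 size factors (adjusted p = 0.0505) or at resolution 0.5 (adjusted p = 0.0526). Clusters 10 and 0 held 25.9% and 17.5% of T-like cells with rice in subject A, where cluster 0 held 55.9% untreated. In subject B cluster 1 held 42.4% with rice and 38.6% untreated.

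NK-like cells raised activation genes and cytokines with rice. CRTAM, an adhesion receptor of activated lymphocytes, rose by 2.13 ± 0.25, TMEM107 by 2.35 ± 0.32, WDR74 by 2.11 ± 0.27 and FEZ1 by 2.04 ± 0.14. RHOBTB3 (-1.27 ± 0.18), TBC1D2B (-1.0 ± 0.22), the signalling kinase SYK (-0.90 ± 0.22) and the proton channel HVCN1 (-0.86 ± 0.17) fell. T cell activation genes rose in 5 of 12 (7 adjusted over the list alone), TNFRSF4 by 1.04 ± 0.15 and CD69 by 0.89 ± 0.13 (list median 0.73, adjusted p = 2.62e-11, and adjusted p = 0.0613 with an estimated correlation). T helper cytokines rose in 3 of 4 (3 adjusted over the list alone), IFNG by 1.73 ± 0.24 (list median 1.38, adjusted p = 3.42e-08, and adjusted p = 0.112 with an estimated correlation). Among cytotoxic effectors 1 of 14 rose (1 adjusted over the list alone), GZMA by 0.57 ± 0.12, and the list was not called (list median 0.10, adjusted p = 0.15). In all, 216 genes were called, 190 up and 26 down. Without the subject block edgeR called 0 (402 at an unadjusted p under 0.05), and DESeq2 called 50 with it. The count was 410 and 388 without the LPS libraries of A and B, 95 and 126 without the rice libraries of A and B, and 142 without the untreated library of subject A. TBC1D2B and SYK lost their calls without untreated A, rice A or rice B, and HVCN1 without untreated B, rice A or rice B (adjusted p = 0.0901 to 0.525), and DESeq2 did not call these or WDR74 (adjusted p = 0.148 to 0.754). SYK was not called with doublets kept (adjusted p = 0.077) or with the automatic threshold (adjusted p = 0.0573). Clusters 8 and 26 held 47.3% and 38.8% of NK-like cells with rice in subject A, against 85.3% and 1.1% untreated.

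B-like cells had 7 genes called with rice, all up, among them the amino acid transporter subunit SLC3A2 (0.81 ± 0.09, from 361 ± 154 to 621 ± 216 CPM) and the iron-storing FTL (0.71 ± 0.09). B cell activation and proliferation genes had no call, also adjusted over the list alone, with medians of 0.18 and 0.06 (adjusted p = 0.208 and adjusted p = 0.57). The count was 313 and 309 without the LPS libraries of A and B, 94 and 26 without the rice libraries, and 2 and 29 without the untreated libraries. SLC3A2 (adjusted p = 0.0999) and FTL (adjusted p = 0.0802) lost their calls without the untreated library of subject A. Without the subject block edgeR called 0 (137 at an unadjusted p under 0.05), and DESeq2 called 8 with it.

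Genes moved by both LPS and rice were counted. In monocyte-like cells 865 genes rose with both and 363 fell with both, where independent calls would give 183 and 58.8, and 3 genes (FTL, PPARG and SLC26A2) fell with LPS and rose with rice. In T-like cells 90 rose and 4 (WAKMAR2, CTSD, MAP2K6 and AL034550.2) fell with both (2.52 and 0.0156 if independent), in NK-like cells 107 and 13 (6.70 and 0.186), and in B-like cells 4 (IFI44, IFIT1, IFIT3 and RSAD2) rose and none fell (0.0670). The genes in brackets were named after their values were seen. Simulated unchanged groups sharing the untreated libraries gave at most 1 shared call. Their mean calls per contrast were 0 to 0.11, so they say little on overlap from a shifted untreated library. Across genes the log2 fold changes correlated at 0.870 in monocyte-like cells, against 0.385 in the simulations. In B-like cells the correlation of 0.462 was no higher than the simulated 0.482, while the covariance was 0.0137 against 0.00698. Genes are not independent replicates.

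The monocyte-like overlap of 1228 genes was 613 and 811 without the rice libraries of A and B, and 804 without the untreated library of subject B. In T-like cells the 94 shared genes became 176 and 220 without the LPS libraries of A and B, 8 and 54 without the rice libraries, and 3 without the untreated library of subject A. In NK-like cells 120 became 70 and 55 without the rice libraries, and 80 without the untreated library of subject A. In B-like cells 4 became 42 and 138 without the LPS libraries, 36 and 10 without the rice libraries, and 2 and 23 without the untreated libraries.

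**Figure D2:**
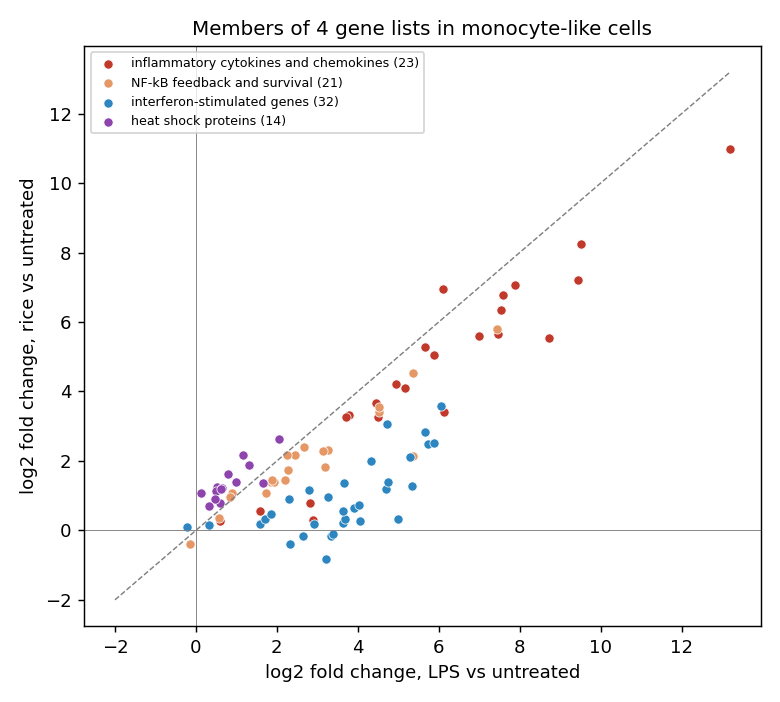
Log2 fold change against untreated with LPS (x axis) and with rice (y axis) in monocyte-like cells, 1 point per gene for cytokines and chemokines (23 genes), NF-kB targets (21), interferon-stimulated genes (32) and heat shock proteins (14), with equal change as a dashed line. Interferon-stimulated genes lie far below the line (medians 3.64 with LPS and 0.59 with rice) and heat shock proteins mostly above it (0.64 and 1.24), while

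Rice against LPS asked how the food response differed from the bacterial one. In monocyte-like cells interferon-stimulated genes were far lower with rice. MX1, an antiviral GTPase, fell by 3.51 ± 0.51, from 258 ± 240.2 to 17.4 ± 0.0716 CPM, as did RSAD2 (-3.42 ± 0.47) and CXCL10, the interferon-driven chemokine (-4.66 ± 0.86). OAS1 (-4.03 ± 0.60), OAS2 (-3.80 ± 0.51), HERC6 (-3.59 ± 0.65), IFIT1 (-3.52 ± 0.59) and XAF1 (-3.48 ± 0.52) were among the lowest as well. Of 32 interferon-stimulated genes 26 fell and none rose (30 fell adjusted over the list alone, median -2.96, adjusted p = 2.56e-65, and adjusted p = 0.279 with an estimated correlation). IL2RA, the interleukin 2 receptor chain, fell by 5.43 ± 0.46, and IL12B was at least 44.0-fold lower, with no UMI with rice. Of 24 cytokine genes 10 fell and none rose (16 adjusted over the list alone), with a median of -1.14 also with IL12B at its bound (adjusted p = 4.1e-24, and adjusted p = 0.279 with an estimated correlation). IL36G (-3.18 ± 0.30), IL23A (-2.72 ± 0.49), IL6 (-2.21 ± 0.21) and IL1B (-1.21 ± 0.17) fell.

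NF-kB targets fell in 3 of 21 (11 adjusted over the list alone), BIRC3 (-1.35 ± 0.25), CD40 (-3.22 ± 0.34) and TNIP3 (-1.64 ± 0.21) (list median -0.53, adjusted p = 8.69e-09, and adjusted p = 0.492 with an estimated correlation). MHC class II genes fell in 4 of 11 (5 fell and 1 rose adjusted over the list alone), among them HLA-DPB1 (-1.41 ± 0.15) and CD74, the invariant chain (-0.80 ± 0.12) (list median -0.71, adjusted p = 7.11e-06, and adjusted p = 0.279 with an estimated correlation). Heat shock proteins had no single call among 14 (1 rose adjusted over the list alone), but the list was higher with rice (list median 0.58, adjusted p = 0.000272, and adjusted p = 0.515 with an estimated correlation). Oxidative stress genes were likewise higher as a list, with no single call among 14 (2 adjusted over the list alone, median 0.54, adjusted p = 0.00512, and adjusted p = 0.57 with an estimated correlation), and its adjusted p = 0.125 without the block. Immediate early genes rose in 2 of 19 (5 rose and 1 fell adjusted over the list alone), NR4A1 by 1.53 ± 0.31 and EGR3 by 1.51 ± 0.31 (list median 0.30, adjusted p = 0.00281, and adjusted p = 0.279 with an estimated correlation). The other lists were not called. Of alarmins, 0 rose and 0 fell of 18 (0 and 0 adjusted over the list alone, median -0.00449, adjusted p = 0.821). Of inflammasome genes, 0 rose and 1 fell of 10 (1 and 1 adjusted over the list alone, median -0.18, adjusted p = 0.579), NLRP3 falling by 1.39 ± 0.23. Of fatty acid genes, 2 rose and 0 fell of 11 (2 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0559), PLIN2 rising by 1.69 ± 0.25. Of cholesterol genes, 0 rose and 0 fell of 14 (1 and 1 adjusted over the list alone, median -0.32, adjusted p = 0.579). Of metal genes, 1 rose and 0 fell of 9 (1 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.0552), FTL rising by 0.85 ± 0.09. Of glycolysis genes, 0 rose and 0 fell of 20 (1 and 0 adjusted over the list alone, median 0.05, adjusted p = 0.504). Of unfolded protein genes, 0 rose and 0 fell of 14 (0 and 0 adjusted over the list alone, median -0.39, adjusted p = 0.267).

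The genes highest with rice over LPS in monocyte-like cells were SLC16A10, an aromatic amino acid transporter (2.65 ± 0.31), KLHL24 (2.34 ± 0.26), IFITM10 (2.31 ± 0.47), HIF1A-AS3 (2.23 ± 0.30), the metal transporter SLC11A1 (2.03 ± 0.21), ANKRD10 (2.02 ± 0.25), SLC26A2 (2.00 ± 0.25), JAKMIP2 (1.88 ± 0.28), GFOD1 (1.87 ± 0.26) and MOAP1 (1.82 ± 0.27). In all 192 genes were called, 56 up and 136 down, and 1 without the subject block, IL2RA. The count was 292 without the LPS library of subject A, 32 without the rice library of subject B, and 514 and 517 without the untreated libraries of A and B. Without rice B the calls of SLC16A10, IFITM10, ANKRD10, SLC26A2, JAKMIP2, GFOD1, MOAP1, IL12B, CXCL10, OAS1, OAS2 and HERC6 ended. Without LPS A those of HIF1A-AS3, IFITM10, OAS1, HERC6 and IFIT1 ended. Without LPS B those of GFOD1, IL12B and CXCL10 did, and without rice A those of HIF1A-AS3, IFITM10 and HERC6. DESeq2 did not call IL12B, CXCL10 or HERC6 (the lowest adjusted p = 0.204). IFITM10 was not called with DESeq2 size factors, at resolution 0.5 or with the automatic doublet threshold (adjusted p = 0.0559 to 0.0748). At resolution 0.5 IL12B was not fitted and IL2RA not called (-3.00, adjusted p = 0.0950).

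T-like cells had 9 genes called between rice and LPS. OAS1 (-4.16 ± 0.33), IFI44L (-4.10 ± 0.34), IFIT3 (-3.82 ± 0.37) and OAS3 (-3.41 ± 0.25) fell, while HSPA1A rose by 1.98 ± 0.19. Of 32 interferon-stimulated genes 5 fell (32 adjusted over the list alone, median -2.68, adjusted p = 1.81e-115, and adjusted p = 0.101 with an estimated correlation). T helper cytokines had no call among 4 (4 fell adjusted over the list alone, median -0.61, adjusted p = 1.88e-06, and adjusted p = 0.101 with an estimated correlation), nor T cell activation genes among 18 (3 fell adjusted over the list alone, median -0.29, adjusted p = 8.07e-07, and adjusted p = 0.11 with an estimated correlation). Proliferation genes had none among 19 (1 rose adjusted over the list alone, median 0.08, adjusted p = 0.0423, and adjusted p = 0.255 with an estimated correlation), and that list had an adjusted p = 0.0632 without the block. Cytotoxic effectors had none, also adjusted over the list alone (list median 0.04, adjusted p = 0.258). The count was 62 and 389 without the LPS libraries of A and B, 1 and 16 without the rice libraries, and 70 and 72 without the untreated libraries. Without rice A all 5 named genes lost their calls (adjusted p = 0.0841 to 0.848), and without rice B IFI44L, IFIT3 and OAS3 did (adjusted p = 0.0595 to 0.114). Without the block edgeR called 0 (306 at an unadjusted p under 0.05), and DESeq2 called 99 with it.

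In NK-like cells RSAD2 (-5.26 ± 0.24), IFIT1 (-4.61 ± 0.32), IFI44L (-4.37 ± 0.33) and OAS1 (-4.36 ± 0.31) fell with rice against LPS. WDR74 rose by 1.71 ± 0.28, the glucocorticoid-induced TSC22D3 by 1.25 ± 0.19, the nuclear receptor NR4A2 by 1.24 ± 0.21 and the chaperone DNAJB1 by 1.17 ± 0.16. T cell activation genes fell in 2 of 12 (7 adjusted over the list alone), among them CD38 (-0.96 ± 0.20) (list median -0.35, adjusted p = 2.02e-05, and adjusted p = 0.125 with an estimated correlation). T helper cytokines had no call among 4 (2 fell adjusted over the list alone, median -0.59, adjusted p = 0.0399, and adjusted p = 0.361 with an estimated correlation), and that list had an adjusted p = 0.0556 without the block. Cytotoxic effectors fell in 2 of 14 (2 adjusted over the list alone), among them GZMB (-0.41 ± 0.09), and the list was not called (list median -0.09, adjusted p = 0.101). In all 160 genes were called, 38 up and 122 down. Without the block edgeR called 0 (346 at an unadjusted p under 0.05), and DESeq2 called 52 with it. The count was 103 and 270 without the LPS libraries of A and B, 68 without the rice library of subject A, and 264 and 268 without the untreated libraries. TSC22D3 and NR4A2 lost their calls without rice A (adjusted p = 0.063), and DESeq2 called neither NR4A2 nor WDR74 (adjusted p = 0.478 and adjusted p = 0.552).

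In B-like cells RSAD2 (-5.43 ± 0.20), IFIT1 (-4.99 ± 0.16), IFIT3 (-4.49 ± 0.20) and CMPK2 (-4.31 ± 0.23) fell with rice against LPS. LRMP rose by 0.79 ± 0.14, BHLHE41 by 0.73 ± 0.14, ARID5B by 0.67 ± 0.11 and FTL by 0.62 ± 0.09. B cell activation genes had no call among 12 (3 fell adjusted over the list alone, median -0.25, adjusted p = 0.00113, and adjusted p = 0.309 with an estimated correlation), and proliferation genes had none, also adjusted over the list alone (list median 0.09, adjusted p = 0.202). In all 87 genes were called, 7 up and 80 down. Without the block edgeR called 0 (242 at an unadjusted p under 0.05), and DESeq2 called 55 with it. The count was 526 without the LPS library of subject B, 264 without the rice library of subject B and 146 without the untreated library of subject B. LRMP (adjusted p = 0.0681) and ARID5B (adjusted p = 0.0702) lost their calls without rice B, and BHLHE41 without untreated A, LPS A or rice A (adjusted p = 0.0546 to 0.243). DESeq2 did not call BHLHE41 (adjusted p = 0.162) or ARID5B (adjusted p = 0.0532). With the stricter cell filter LRMP, ARID5B and BHLHE41 were not called (adjusted p = 0.0577, 0.0846 and 0.0758), nor were LRMP and BHLHE41 at resolution 0.5 (adjusted p = 0.0519 and 0.0588). BHLHE41 was also not called with only the 4 libraries compared (adjusted p = 0.0551) or with doublets kept (adjusted p = 0.0562).

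Cow milk, given to subject A alone, left monocyte-like cells close to untreated, with inflammatory genes a little lower. CXCL8 stood at 1751 CPM (1700.3 to 1802) against 3025 (2973 to 3078) untreated, where brackets hold Poisson 95% intervals. PTX3, a secreted pattern-recognition protein, stood at 61.2 CPM (52 to 71.5) against 156 (144 to 168). The other lowest genes, with CPM for milk and untreated, were TNFAIP6 (52.3 and 112), AHR (58.5 and 122), DNAJB4 (57.3 and 117), CXCL2 (91.6 and 179), G0S2 (158 and 301) and SLAMF7 (132 and 229). Among the highest were IRF2BPL (131 and 84.7), SNAI1 (101 and 66.9), UBASH3B (102 and 68.5), HECA (198 and 138), RCC2 (125 and 86.6), HEXA (244 and 176) and IER3 (885 and 659.7). Of 23 cytokine genes 4 were higher than untreated (median log2 ratio -0.44, percentile 0), and against LPS the median was -4.05. NF-kB targets (median -0.28, percentile 0.01), heat shock proteins (median -0.45, percentile 0) and interferon-stimulated genes (median -0.20, percentile 0) were lower too. In T-like cells the highest were ID3 (103 and 80.6), PMEPA1 (239 and 193), CREM (404 and 329) and ATP1B3 (109.9 and 89.9), and the lowest LRRN3 (149.9 and 212), IPCEF1 (106 and 146), SMC4 (118 and 156) and SLFN5 (161 and 210.2). Cluster 13 held 99.6% of the milk monocyte-like cells.

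Almond butter, also given to subject A alone, had higher levels of part of the cytokine set in monocyte-like cells and of chaperones in T-like cells. In monocyte-like cells IL1B stood at 3279 CPM (3210.1 to 3349) against 198 (185 to 212) untreated, and INHBA stood at 328 CPM (306 to 351) against 1.64 (0.66 to 3.38) untreated. The other highest genes, with CPM for almond butter and untreated, were CCL3 (1899 and 39.4), CCL4L2 (569 and 11.7), CCL4 (1921 and 73.9), CXCL3 (683 and 31.7), GEM (143 and 4.46) and CCL3L1 (376 and 27.9). The lowest were STX6 (24.9 and 119.9), GAPT (44.7 and 192), FUCA1 (26 and 119), TSHZ1 (37.5 and 157), INAFM2 (30.6 and 131), RGS19 (25.2 and 108), CXCR4 (185 and 597) and ORAI2 (61.2 and 202). Of 23 cytokine genes 19 were higher (median log2 ratio 1.75, percentile 100), though the median against LPS was -2.37. Heat shock proteins were higher in all 14 (median log2 ratio 0.85, percentile 100), and inflammasome genes stood at 0.50 (percentile 99.91). NF-kB targets (median 0.07, percentile 90) and interferon-stimulated genes (median -0.26, percentile 14.5) lay within the range of random lists. Cluster 13 held 77.1% of these cells and cluster 22 22.9%.

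In T-like cells of the almond butter well HSPA1A stood at 719.8 CPM (708 to 731) against 45.8 (43.8 to 47.8) untreated. The other highest genes, with CPM for almond butter and untreated, were HSPA1B (101 and 6.52), HSPH1 (475 and 66) and HSP90AB1 (2194 and 391), all chaperones. The lowest were the metallothioneins MT2A (88.8 and 569.9) and MT1X (36.8 and 254), the T cell receptor kinase LCK (140 and 402) and the receptor subunit CD3G (375 and 987). As lists, heat shock proteins were higher in all 14 (median 1.87, percentile 100) and metallothioneins and metal transporters lower (median -1.61, percentile 0). Clusters 9 and 10 held 46.6% and 21.6% of these T-like cells, against 1.07% and 1.27% of the untreated ones. The median of all genes was -0.18 in T-like cells and -0.16 in monocyte-like cells, to which these list medians compare.

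Scrambled eggs, given to subject B alone, were followed by higher monocyte-attracting chemokines and by much lower chaperones. In monocyte-like cells CCL2 stood at 495 CPM (472 to 519) against 131 (119 to 143) untreated, and CCL4 stood at 380.1 CPM (359.9 to 401) against 42.4 (36 to 49.7) untreated, below its 7122 CPM with LPS. The other highest genes, with CPM for eggs and untreated, were DUSP6 (412 and 54.5), CCL4L2 (136 and 15.3), AHR (256 and 42.2), LPAR6 (113 and 17), TLR2 (120.4 and 27.9) and PLA2G7 (148 and 38.1). HSPA1A stood at 26.2 CPM (21.1 to 32.1) against 347 (328 to 367), and the other lowest were HSPH1 (35 and 341), SNAI1 (6.83 and 109), HSPA8 (146 and 1019), CYP1A1 (19.1 and 146), GZF1 (19.9 and 132), FOSB (51.5 and 268) and GFOD1 (22.8 and 132). Of 23 cytokine genes 17 were higher (median log2 ratio 0.31, percentile 99.98), with a median against LPS of -4.19. NF-kB targets (median 0.24, percentile 99.81) and inflammasome genes (median 0.52, percentile 99.75) were slightly higher, and no heat shock gene of 14 was (median -1.57, percentile 0). In T-like cells the lowest were the metallothioneins MT1E (34.6 and 397), MT2A (363 and 2003) and MT1X (141 and 727) and CREM (201 and 1142). The highest were the mitochondrial carrier UCP2 (106 and 23.5), RIPOR2 (293 and 141), the costimulatory receptor CD27 (173 and 82.4) and ACTG1 (350.5 and 174). Metallothioneins and metal transporters (median -2.13, percentile 0) and heat shock proteins (median -0.92, percentile 0) were both lower there. Cluster 7 held 52.8% of T-like cells with eggs and 2.99% untreated.

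Set beside them in the same way, rice gave a cytokine median of 3.27 in subject A and 2.57 in subject B, and LPS gave 3.54 and 4.73. With rice IL1B stood at 14204 CPM in subject A and 9967 in subject B, against 198 and 177 untreated. Heat shock medians in monocyte-like cells were 0.93 and 1.01 with rice, and interferon medians 0.21 and 0.11. With LPS the interferon medians were 2.82 and 1.73. In T-like cells rice gave heat shock medians of 1.01 and 0.11 and metallothionein medians of -0.74 and -0.79. Differences between foods were not tested.

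**Figure D3:**
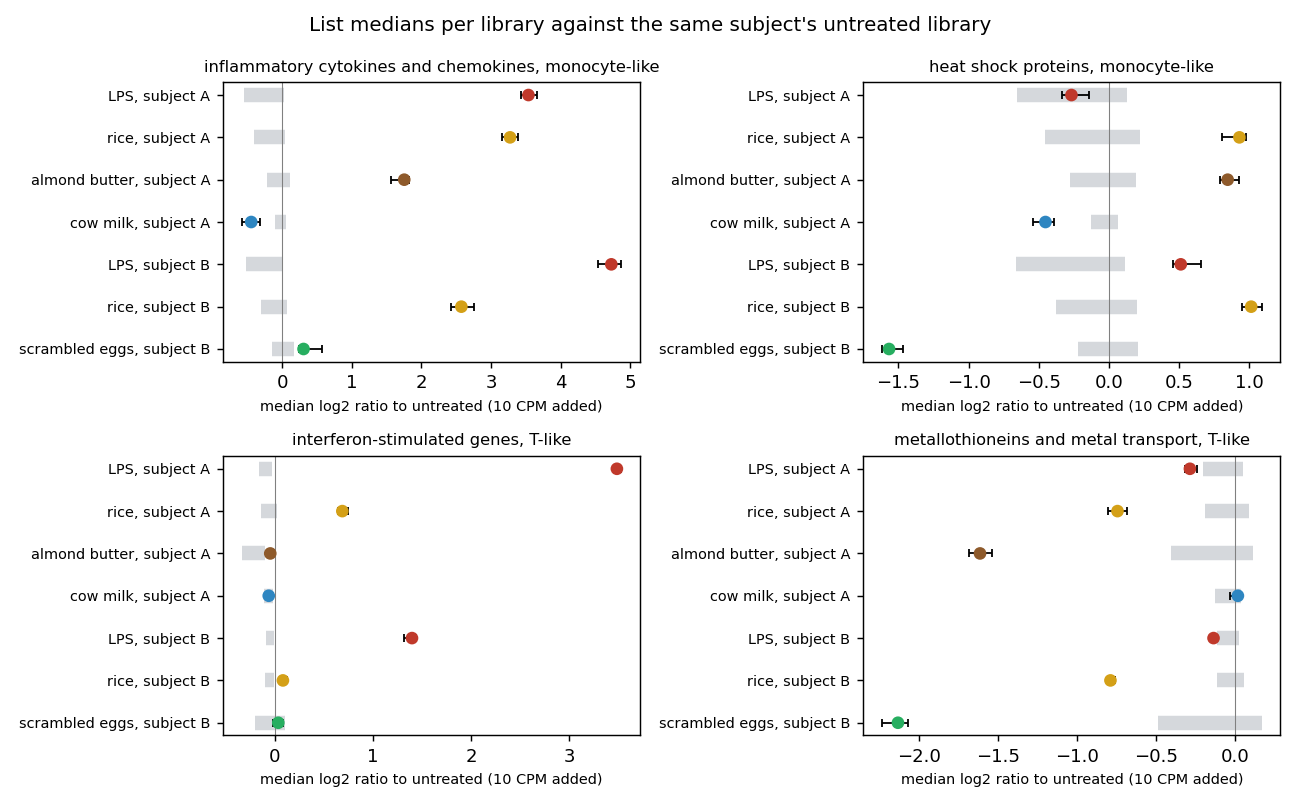
Median log2 ratio to untreated of the same subject (10 CPM added) for 4 gene lists in monocyte-like or T-like cells, 1 panel per list and 1 point per library, with black bars for Poisson redraws of the counts and grey bands for the 95% range of random matched lists. For cytokines in monocyte-like cells, LPS, rice, almond butter (1.75) and eggs lie above the band and milk below it (-0.44).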

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

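The doublets-by-automatic-threshold alternative and the 4 lists carried into further classes were chosen only after the data were seen, and the other alternatives before. With 2 libraries per treatment and 2 residual degrees of freedom, counts of called genes are the least settled values here, above all in T-like, NK-like and B-like cells. In monocyte-like cells the count of genes called with LPS stayed within 1.5 times of 2755 under every setting but DESeq2 and 1 left-out library. Among the 119 named genes no fold change changed sign in any setting that fitted them, and at resolution 0.5 IL12B was not fitted, which left 117. The cause of the changes below was not tested, except where fewer libraries or more genes in a fit define the setting.

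Left out in turn, the 6 libraries gave these ranges of called genes for LPS against untreated, rice against untreated and rice against LPS: 1743 to 3019, 668 to 1793 and 32 to 517 in monocyte-like cells, 83 to 779, 3 to 441 and 1 to 389 in T-like cells, 248 to 432, 95 to 410 and 68 to 270 in NK-like cells, and 35 to 717, 2 to 313 and 59 to 526 in B-like cells. The overlap of LPS and rice ranged from 613 to 1367 in monocyte-like, 3 to 220 in T-like, 55 to 152 in NK-like and 2 to 138 in B-like cells. Of the named genes, 24 lost their call without rice A, 27 without rice B, 16 without untreated A, 10 without LPS A, 4 without LPS B and 3 without untreated B.

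Without the subject block, called genes in the same 3 contrasts numbered 0, 0 and 0 in T-like and in B-like cells and 6, 0 and 0 in NK-like cells. In monocyte-like cells rice against untreated gave 697 and rice against LPS 1. The overlap was 630 in monocyte-like cells and 0 in the others, and 80 of the 119 named genes lost their call. Of 105 list tests 8 lost theirs in the same direction and 1 gained one. A further 1, the metallothioneins in B-like cells with rice, lost its call and turned direction (adjusted p = 0.524). Counting only the lists planned for a class, those called between rice and LPS in NK-like cells fell from 2 to 1.

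With DESeq2 the counts were 1759 in monocyte-like cells with LPS, 278 with rice and 99 between rice and LPS in T-like cells, and 142, 50 and 52 over the 3 contrasts in NK-like cells. In B-like cells they were 66 with LPS and 55 between rice and LPS. The overlap was 156 in T-like, 34 in NK-like and 2 in B-like cells, and 16 named genes were not called. DESeq2 size factors moved no count over 1.5 times and ended the call of 2 named genes. With no filter on low counts the counts were 894, 628 and 376 in T-like cells, 406, 244 and 343 in B-like cells, 248 between rice and LPS in NK-like cells and 714 in monocyte-like cells. The overlap was then 340 in T-like and 99 in B-like cells. The median log2 fold change in monocyte-like cells was then -0.12 with LPS and -0.15 with rice, where the main fit gave -0.0263 and -0.0275. With only the 4 libraries compared, the counts were 228, 367 and 69 in T-like cells, 165 with LPS and 308 with rice in B-like cells, and 275 between rice and LPS in NK-like cells, with overlaps of 150 in T-like and 46 in B-like cells.

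With doublets kept the counts were 179 in T-like cells with rice, 30 between rice and LPS, and 140 in NK-like cells with rice. With the automatic threshold they were 180 and 30 in T-like cells. The stricter cell filter gave 4 genes and an overlap of 2 in B-like cells with rice, and a monocyte-like share of 5.46% with eggs, and it moved 41 of 90 class shares beyond their interval. Clustering at resolution 0.5 gave 118 genes between rice and LPS in monocyte-like cells, and cytokine medians of -4.31 for milk and -4.28 for eggs against LPS and 3.39 for rice in subject B against untreated. With an estimated correlation, the planned lists called fell to 1 in T-like cells with LPS. They fell to 0 in monocyte-like cells in all 3 contrasts, in T-like and NK-like cells with rice and between rice and LPS, and in B-like cells with LPS and between rice and LPS. Of the lists added later, heat shock proteins in NK-like cells with rice stayed called.

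Adding 1 CPM in place of 10 gave cytokine medians against untreated of 4.15 and 3.74 for rice in A and B, 2.11 for almond butter and 0.72 for eggs, and against LPS of -5.16 for milk, -2.67 for almond butter and -4.68 for eggs. With 50 CPM they were 3.04 and 2.18 for rice, 1.17 for almond butter, 0.17 for eggs and -0.23 for milk against untreated. Against LPS they were -0.37 and -1.10 for rice, -1.64 for almond butter, -3.07 for eggs and -3.59 for milk. None of these changed sign. Of 350 list medians, 102 moved beyond their counting interval with 1 CPM, 144 with 50 CPM, 28 with doublets kept, 25 with the automatic threshold, 20 at resolution 0.5 and 14 with the stricter filter.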

Other observations

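The mixture test below was chosen only after the result was seen, and the lists for further classes after the data were seen. Neutrophil-like cells were a larger share of the food and LPS libraries than of the untreated ones, milk apart. In subject A they made up 0.345% (0.224% to 0.51%) of cells untreated, 1.86% with LPS, 1.95% with rice, 0.393% with milk and 4.72% (4.07% to 5.44%) with almond butter. In subject B they made up 0.132% (0.057% to 0.26%) untreated, 0.38% with LPS, 2.12% with rice and 3.82% (3.3% to 4.4%) with eggs. Their median depth was 639 to 1324 UMIs, and only 14 of the 186 egg cells had 1000 UMIs or more, against 134 of 182 with almond butter. Conventional-dendritic-like cells held 0.442% and 0.363% untreated and, with LPS, 0 of 4739 cells in subject A (up to 0.0633%, 3 counts of the total) and 2 in subject B. At resolution 0.5 the LPS libraries held 18 and 11 and IL2RA shrank between rice and LPS, so LPS monocyte-like IL12B, IL2RA and MHC class II may be partly dendritic-like. Plasmacytoid-dendritic-like cells held 0.242% to 0.707%, platelet-like cells 0.231% to 0.674% and plasma-cell-like cells 0.0259% to 0.276%, and 0.698% to 2.76% of cells stayed unnamed.

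In lymphocytes the interferon list was called in NK-like (29 up and 0 down of 31, 30 and 0 adjusted over the list alone, median 2.63, adjusted p = 4.78e-227, and adjusted p = 0.0736 with an estimated correlation) and B-like cells (26 up and 0 down of 30, 30 and 0 adjusted over the list alone, median 3.69, adjusted p = 5.17e-308, and adjusted p = 0.0514 with an estimated correlation) with LPS. It was called with rice too in NK-like (4 up and 0 down of 31, 9 and 0 adjusted over the list alone, median 0.47, adjusted p = 5.1e-07, and adjusted p = 0.364 with an estimated correlation) and B-like cells (4 up and 0 down of 30, 11 and 0 adjusted over the list alone, median 0.80, adjusted p = 9.54e-22, and adjusted p = 0.328 with an estimated correlation). Against LPS, rice had it lower in NK-like (0 up and 29 down of 31, 0 and 30 adjusted over the list alone, median -2.24, adjusted p = 1.07e-235, and adjusted p = 0.0669 with an estimated correlation) and B-like cells (0 up and 26 down of 30, 0 and 30 adjusted over the list alone, median -2.92, adjusted p = 1.13e-257, and adjusted p = 0.0608 with an estimated correlation). Heat shock proteins were called higher as a list with rice in T-like (2 up and 0 down of 14, 13 and 0 adjusted over the list alone, median 0.70, adjusted p = 9.04e-17, and adjusted p = 0.19 with an estimated correlation), NK-like (7 up and 0 down of 13, 11 and 0 adjusted over the list alone, median 0.47, adjusted p = 8.98e-17, and adjusted p = 0.0495 with an estimated correlation) and B-like cells (0 up and 0 down of 14, 1 and 0 adjusted over the list alone, median 0.35, adjusted p = 1.49e-06, and adjusted p = 0.34 with an estimated correlation). In T-like cells heat shock proteins rose with rice mainly in subject A, by their median, and little in subject B. With LPS they were called higher in NK-like cells (3 up and 0 down of 13, 6 and 0 adjusted over the list alone, median 0.34, adjusted p = 2.29e-05, and adjusted p = 0.122 with an estimated correlation) and were not called in T-like (0 up and 0 down of 14, 0 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.516) or B-like cells (0 up and 0 down of 14, 0 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.319). Rice against LPS had them higher in T-like (1 up and 0 down of 14, 10 and 0 adjusted over the list alone, median 0.66, adjusted p = 1.07e-18, and adjusted p = 0.174 with an estimated correlation), NK-like (2 up and 0 down of 13, 3 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.003, and adjusted p = 0.168 with an estimated correlation) and B-like cells (0 up and 0 down of 14, 0 and 0 adjusted over the list alone, median 0.29, adjusted p = 0.00148, and adjusted p = 0.526 with an estimated correlation), the last with an adjusted p = 0.0694 without the subject block.

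Metallothioneins and metal transporters were called lower as a list with rice in T-like (0 up and 3 down of 12, 1 and 7 adjusted over the list alone, median -0.92, adjusted p = 2.67e-08, and adjusted p = 0.0817 with an estimated correlation) and B-like cells (1 up and 0 down of 10, 2 and 5 adjusted over the list alone, median -0.25, adjusted p = 0.0437, and adjusted p = 0.328 with an estimated correlation). Without the block they were not called in T-like cells (adjusted p = 0.364), and in B-like cells, where no single member was called lower, the direction turned (adjusted p = 0.524). They were not called in NK-like cells (1 up and 0 down of 10, 2 and 2 adjusted over the list alone, median -0.26, adjusted p = 0.189). With LPS they were not called in T-like (0 up and 0 down of 12, 0 and 3 adjusted over the list alone, median -0.12, adjusted p = 0.0976), NK-like (1 up and 0 down of 10, 1 and 0 adjusted over the list alone, median -0.14, adjusted p = 0.349) or B-like cells (0 up and 0 down of 10, 0 and 0 adjusted over the list alone, median -0.08, adjusted p = 0.267). Between rice and LPS they were lower in T-like cells (0 up and 0 down of 12, 1 and 6 adjusted over the list alone, median -0.59, adjusted p = 5.17e-05, and adjusted p = 0.146 with an estimated correlation), where the call ended without the block (adjusted p = 0.777), and not called in NK-like (0 up and 1 down of 10, 2 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.868) or B-like cells (1 up and 0 down of 10, 1 and 1 adjusted over the list alone, median -0.07, adjusted p = 0.586). Immediate early genes were called higher as a list with LPS in T-like (3 up and 0 down of 19, 5 and 0 adjusted over the list alone, median 0.20, adjusted p = 4.75e-05, and adjusted p = 0.436 with an estimated correlation), NK-like (5 up and 0 down of 17, 5 and 0 adjusted over the list alone, median 0.25, adjusted p = 2.29e-05, and adjusted p = 0.292 with an estimated correlation) and B-like cells (1 up and 0 down of 19, 6 and 0 adjusted over the list alone, median 0.22, adjusted p = 0.000297, and adjusted p = 0.248 with an estimated correlation), and with rice in T-like (1 up and 0 down of 19, 6 and 0 adjusted over the list alone, median 0.34, adjusted p = 3.98e-08, and adjusted p = 0.21 with an estimated correlation) and NK-like cells (8 up and 0 down of 17, 10 and 0 adjusted over the list alone, median 0.56, adjusted p = 9.98e-18, and adjusted p = 0.141 with an estimated correlation) but without a call in B-like cells (0 up and 0 down of 19, 0 and 0 adjusted over the list alone, median 0.03, adjusted p = 0.0695). Between rice and LPS they were higher in NK-like (2 up and 0 down of 17, 6 and 1 adjusted over the list alone, median 0.23, adjusted p = 0.00176, and adjusted p = 0.382 with an estimated correlation), lower in B-like (0 up and 0 down of 19, 0 and 3 adjusted over the list alone, median -0.11, adjusted p = 0.0189, and adjusted p = 0.472 with an estimated correlation) and not called in T-like cells (0 up and 0 down of 19, 0 and 0 adjusted over the list alone, median 0.02, adjusted p = 0.439). Without the block the B-like call ended (adjusted p = 0.0694). In the single foods, heat shock medians with almond butter and eggs were 0.95 and -2.34 in B-like and 1.07 and -0.77 in NK-like cells. Metallothionein medians were -1.02 and -2.48 in B-like and -0.77 and -1.64 in NK-like cells. Egg B-like cells lay mostly in cluster 15 (88.1%) and almond butter NK-like cells in cluster 26 (84.2%), against clusters 3 (91.6%) and 8 (85.3%) in the same subject's untreated ones.

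Metallothioneins were far lower with eggs than untreated in T-like cells of subject B, and 2 explanations were tested. T-like MT2A also fell with almond butter (88.8 from 569.9 CPM) and rice, so the drop is not special to eggs. A change in which T-like cells were recovered is argued against by MT2A in the other lymphocytes. Its egg to untreated ratio was 0.0648 in B-like, 0.275 in NK-like and 0.181 in T-like cells. Less free zinc in the egg well, which metallothioneins and the zinc exporter SLC30A1 both respond to, stays a candidate. T-like SLC30A1 stood at 7.16 CPM (6.15 to 8.29) against 65.2 (62.4 to 68.1), a ratio of 0.110. That does not decide it: T-like CREM fell too (201 from 1142 CPM), and MT2A less in monocyte-like cells (ratio 0.763). With 1 egg well, its other differences stay open.

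With rice, monocyte-like cells might mix cells like those of the LPS and of the untreated well. Such a mixture would reach the same share of the LPS response for every gene group. Rice reached 64.2% (48.1% to 76.7%) and 36.4% (22.1% to 45.2%) of the cytokine response in subjects A and B, but 4.62% (-2.83% to 10.1%) and 6.82% (-1.64% to 15.6%) of the interferon response. These are medians of the list members at least 50 CPM higher with LPS than untreated, 18 and 21 for cytokines and 27 and 10 for interferon. The higher ratio of these shares was 0.187, which argues against this mixture. Untreated-like cells mixed with cells activated without interferon genes stay open, as cluster 13 held 39.3% of rice cells in subject B. Bacterial products in the rice, another dose or timing stay open, since no well tests them.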
